A study of Caenorhabditis elegans with 4 samples.

How the data were processed

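Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on hermaphrodite Caenorhabditis elegans of the strain OP198 at the L3 larval stage, grown at 20 °C. The strain carries a transgene that expresses MML-1, a basic helix-loop-helix leucine zipper transcription factor of the Myc and Mondo family, fused at its C terminus to GFP. Per the labels' protocols, crosslinked chromatin was sonicated, part of each extract was kept as input, and the rest was precipitated with an anti-GFP antibody. There were 4 samples: 2 ChIP samples and 2 input samples, numbered 1 and 2 in each group by their titles. Nothing in the labels says whether the replicates came from separate cultures, so the spread between them may be partly technical.

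Per the file headers, all 3 peak lists use the genome build WormBase WS220. The combined list was deposited with PeakSeq named as its source and gives a q-value for each of 396 peaks, all below 0.01; whether reads of the replicates were pooled for it is not given in the sources used here. Each ChIP replicate's list was deposited with spp_via_IDR named as its source, which refers to the SPP peak caller and to the irreproducible discovery rate framework, and gives a score for each of 30000 peaks; 1 interval of replicate 1, on X, is listed there under the peak numbers 13 and 169, and both entries were kept. The scale of the score is not given, and it was used only to rank peaks within a list. The score reached a ceiling shared by 263 peaks in replicate 1 and by 429 peaks in replicate 2. Each replicate peak also carries a number from 1 to 30000, which followed the score closely (Spearman rho = -1.00 to 2 decimals in both lists) and has no ties. The aligner, the versions, the filters and the control used for each list are not given in the sources used here. Sequencing depth is unknown, since the lists hold no read counts, and no read-level values of the input samples were analysed here. The length of a list affects the overlap computed from it, so shares from the full lists of 30000 peaks and from the first 396 are each set against their own shifts.

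Peaks were compared by position. In the designed ranking, replicate peaks were ordered by score with ties broken by position, and the first 396 were taken from each list to match the combined list. Because of the ceiling, 33 tied replicate 2 peaks fell outside these 396, and all 33 were on X. The ranking by peak number was therefore added after the data were seen, and it is the one used below for rank classes and for the density per chromosome. Overlap of 1 bp or more counted as shared. Chance overlap was taken from 1000 random circular shifts of one list along each chromosome, and the permutation p-values are one-sided, with 0.001 the smallest they can give. Each shift moves all peaks of a chromosome by the same offset. It keeps their spacing but not where they are dense along the chromosome, such as in autosome centres. Chromosome lengths were taken as the span from the first start to the last end over the 3 lists. Counts on X were compared with its share of the summed spans, and counts in the central 33.3% of each autosome with 33.3%, by two-sided exact binomial tests. Intervals of shares are exact Clopper-Pearson 95% intervals, and those of Spearman's rho are approximate 95% intervals from Fisher's z transformation. Intervals, binomial and Fisher tests and the permutation among autosomes treat peaks as independent, although neighbouring peaks cluster, and the intervals cover counting error only. Correlations are across peaks, which are not replicates, and carry no p-value. Families of tests were adjusted by the Benjamini-Hochberg method.

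The overlap and shift code was tested on simulated data: with 396 peaks per list, 3 of 100 unrelated pairs of lists gave a permutation p-value under 0.05, and all 20 pairs with 60 planted shared peaks were called, with a mean excess of 60.0 peaks over the shifts. The simulated peaks were placed uniformly on chromosomes of equal length, without the clusters of the real lists. The test therefore checks the code and does not give the error rate on these data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

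The tests, the alternatives and the rule for the regions named in the text were fixed before the data were examined, except where stated. Under that rule, with no annotation of the same build, the text names the 10 combined peaks with the smallest q-values, the 2 smallest per chromosome, and the peak whose number differed most between replicates. Other regions named below were chosen after their values were seen. The rank classes, the midpoint distances, the balance between replicates, the tests of single chromosomes, the correlation of peak numbers among the first 396 peaks and the test of differences among autosomes were added after the data were seen. The alternatives covered the overlap criterion, the number of peaks taken, the ranking column, a stricter list, each replicate list on its own, and the width of the central part. The 3 designed tests of promoters, of gene lists and of the E-box sequence were not run, because no WS220 genome or annotation was used here and the gene table at hand refers to the assembly WBcel235. For the same reason no gene, exon or promoter is named for any peak.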

Results

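The series mapped where the tagged transcription factor MML-1 was bound in L3 larvae. The data comprised 3 peak lists on WS220: one for each of the 2 anti-GFP ChIP replicates and one combined list. The combined list held 396 peaks with a median width of 273 bp and a range of 1 to 1649 bp, and 48 of them were narrower than 100 bp. It covered 0.124% of the genome span. Each replicate list held 30000 peaks, nearly all of one width. That width was 504 bp for 29957 peaks of replicate 1 and 520 bp for 29978 peaks of replicate 2. The replicate lists covered 13.8% and 14.2% of the genome span. The narrower peaks were among the strongest: 41 of the 43 in replicate 1 and 21 of the 22 in replicate 2 had a peak number of 50 or less. No interval was identical between the replicate lists.

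The strongest binding region lay on chromosome IV at 13394712 to 13395842 and was ranked first in all 3 lists. Its q-value in the combined list was 5.85e-126, a value given by the authors' peak caller as for every q-value below. The second combined peak was on X at 6749008 to 6750613 (q = 4.65e-94), where the strongest overlapping peak was number 12 in replicate 1 and number 9 in replicate 2. Chromosome IV held 3 more of the 10 leading peaks. These lay at 6878790 to 6879654 (q = 2.68e-85), at 11961524 to 11962697 (q = 4.22e-81) and at 3653334 to 3654982 (q = 1.25e-62). On chromosome V the leading peaks were at 12636848 to 12638031 (q = 7.23e-75) and at 19528819 to 19529617 (q = 5.36e-64). The chromosome I peak at 7661830 to 7662542 had q = 2.43e-71, and the chromosome III peak at 6897019 to 6898137 had q = 6.17e-59. The chromosome II peak at 13469005 to 13469984 completed the leading 10 with q = 2.46e-52. All 10 overlapped a peak numbered 18 or lower in both replicates.

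The next peaks in line per chromosome were weaker. On X, the peak at 10331907 to 10332899 had q = 1.62e-47 and overlapped peaks number 21 and 15 of replicates 1 and 2. On I, the peak at 10751505 to 10752387 had q = 8.24e-27, with peak numbers 15 and 19. On III, the peak at 9545760 to 9546312 had q = 9.45e-22, with peak numbers 22 and 16. On II, the peak at 11759200 to 11759643 had q = 3.97e-35 but stood at number 556 in replicate 1 and 106 in replicate 2.

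**Figure D1:**
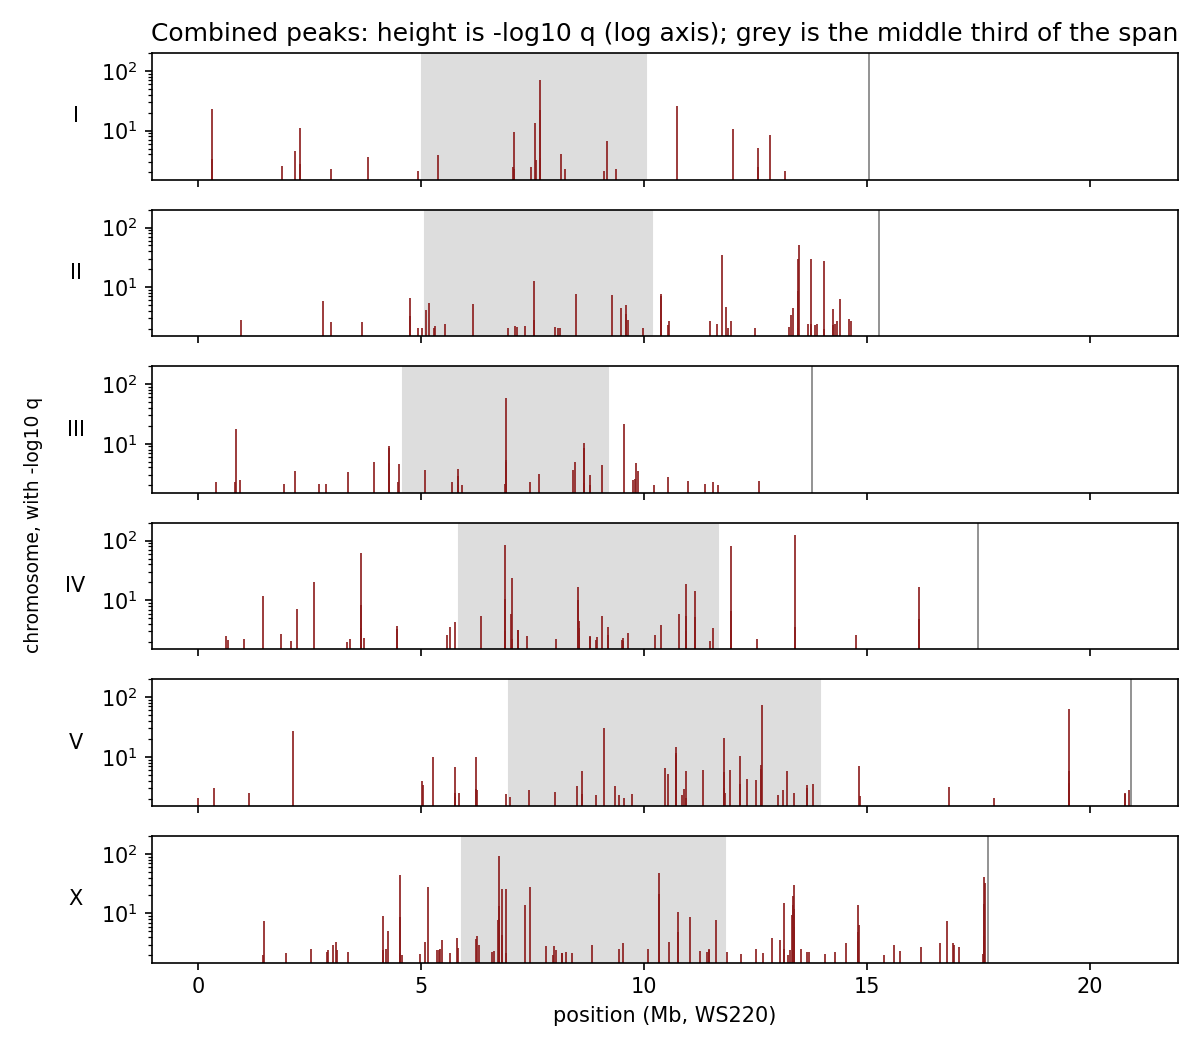
Position of the 396 combined peaks along each chromosome (x axis, Mb on WS220), drawn as vertical lines whose height is -log10 of the q-value on a log axis. Grey shading marks the central 33.3% of each span and the thin vertical line its end; the tallest line is the chromosome IV peak at 13394712 with q = 5.85e-126.

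The first comparison asked how well the ChIP replicates shared their peaks. Sharing was highest among the strongest peaks and fell with rank toward the level of the shifts. Over the full lists, 35.27% of replicate 1 peaks and 35.45% of replicate 2 peaks overlapped the other list. The shifts gave means of 26.1% and 26.3%. Of the first 100 peaks of replicate 1 by peak number, 95 overlapped a peak anywhere in the replicate 2 list (95% interval 88.7 to 98.4%), against a mean of 24.7% over the shifts. In the other direction 85 of 100 overlapped (76.5 to 91.4%), against 25.4%. Among peaks 101 to 396 the shares were 61.5% and 57.4%. Among peaks 20001 to 30000 they were 32.0% and 33.5%, against 26.1% and 26.2% over the shifts. Every rank class exceeded all 1000 shifts in both directions (permutation p = 0.001). Because the shifts do not keep the density of peaks along a chromosome, this excess cannot be read as shared binding alone. That holds most for the weakest class, where the excess was small. When the first 396 peaks of each list were set against each other, 86 peaks of replicate 1 (21.7%) overlapped a replicate 2 peak, against a mean of 1.55 and a highest value of 10 over the shifts (permutation p = 0.001). Ranking by peak number gave 93 peaks (23.5%).

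**Figure D2:**
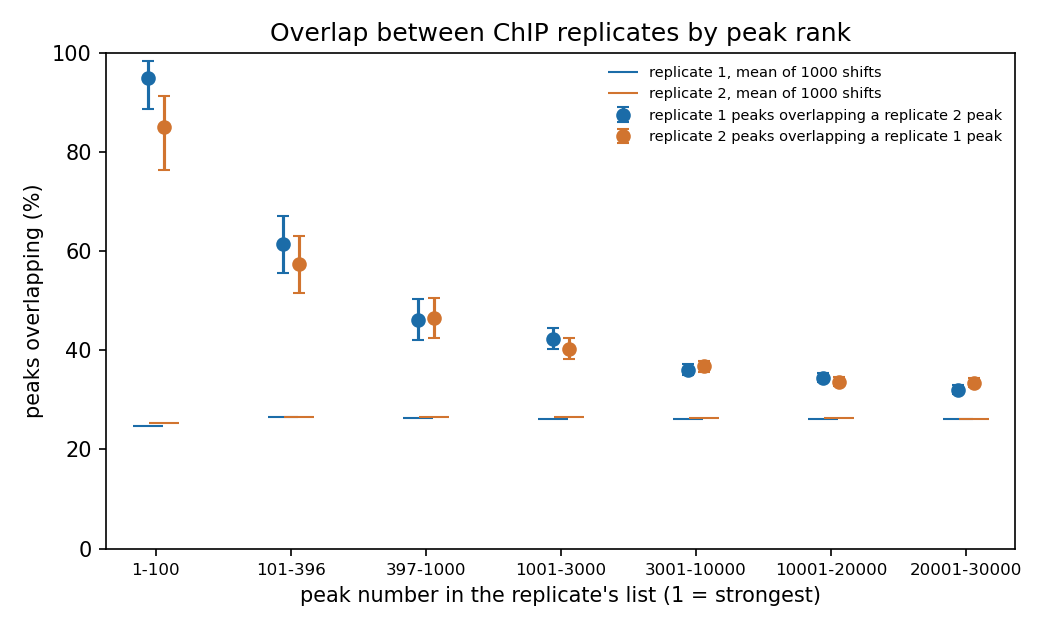
Share of peaks (y axis, %) of each ChIP replicate that overlap any peak of the other replicate, by peak number (x axis, 1 is the strongest). Points are observed shares with exact 95% intervals and horizontal dashes the mean of 1000 circular shifts; the share falls from 95% and 85% in the first 100 peaks to 32.0% and 33.5% in the last class, while the shifts stay between 24.7% and 26.6%.

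Shared strong peaks also agreed in position. For the 50 mutually matched pairs with both members in the first 100, the midpoints lay a median of 12 bp apart and 49 pairs lay within 100 bp. Over all 8931 mutually matched pairs the median distance was 154 bp. The scores of these 8931 pairs were almost unrelated across peaks (Spearman rho = 0.08, 95% interval 0.05 to 0.10). Many of these pairs may be chance overlaps, since 35.27% of all replicate 1 peaks overlapped a replicate 2 peak against 26.1% over the shifts. The low rho and the 154 bp distance therefore need not describe sites bound in both replicates. Among the 239 pairs with a member in the first 396 of replicate 1, rho was 0.30 (0.18 to 0.41), but 180 of these had the tied maximum score in replicate 1. With peak numbers, which have no ties, rho was 0.61 (0.52 to 0.68) over the 240 pairs with a member in the first 396 of replicate 1 and 0.63 (0.54 to 0.70) over the 207 pairs with one in the first 396 of replicate 2.

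The second comparison asked how the combined list related to each replicate. Of the 396 combined peaks, 342 overlapped a peak of replicate 1 (86.4%, 82.6 to 89.6%) and 310 overlapped a peak of replicate 2 (78.3%, 73.9 to 82.2%). The shifts gave means of 21.7% and 22.1%, and neither observed share was reached in any of 1000 (permutation p = 0.001 each). The series has no ChIP samples other than these 2, so the lists describe the same experiments. Overlap beyond the shifts, and the rank correlations below, are therefore not independent support for the combined peaks. Both replicates had a peak at 275 combined peaks, and neither did at 19. Only replicate 1 had one at 67 and only replicate 2 at 35, a difference beyond counting error across peaks (two-sided exact binomial p = 0.00199). The first 396 peaks of replicate 1 were found at 161 combined peaks (40.7%) and those of replicate 2 at 111 (28.0%), or at 160 and 122 when ranked by peak number. The q-value rank of matched combined peaks followed the peak number with a Spearman rho of 0.64 in replicate 1 (342 peaks) and 0.61 in replicate 2 (310 peaks), across peaks. A 50% reciprocal overlap lowered the shares found in the full lists to 41.2% and 35.9%, still above all shifts.

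Single combined peaks differed widely in peak number between replicates. The combined peak with the largest difference in peak number was on X at 4144132 to 4144293 (q = 0.00382), where the overlapping peak was number 472 in replicate 1 and 28571 in replicate 2. The replicate 2 overlap may be by chance, since a mean of 22.1% of combined peaks overlapped a replicate 2 peak over the shifts. A nearby combined peak on X, at 4145988 to 4146394, was number 416 in replicate 1 and 248 in replicate 2. Among stronger regions, picked after their values were seen, the chromosome V peak at 9095453 to 9096213 (q = 9.34e-32) stood at number 30 in replicate 1 and 5196 in replicate 2. The chromosome IV peak at 10935227 to 10935712 (q = 2.25e-19) was number 35 in replicate 1 and overlapped no peak of replicate 2. The next combined peak on IV, at 10935938 to 10936426, was number 47 in replicate 2 and 2219 in replicate 1. The chromosome I peak at 2291054 to 2291763 (q = 5.98e-12) was number 87 in replicate 2 and 4131 in replicate 1. Its neighbour at 2292837 to 2293179 was number 137 in replicate 1 and 7026 in replicate 2. On IV and I the other replicate thus had a strong peak nearby. These differences therefore do not show that a region was missing or weak in 1 replicate.

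In the converse direction, 89 of the first 100 peaks of replicate 1 and 70 of the first 100 of replicate 2 overlapped a combined peak (two-sided Fisher's exact p = 0.00141). These sets are not independent, as the test assumes, since 50 matched pairs had both members in the first 100. The strongest replicate peaks without a combined peak lay close together on X. The peak at 6741934 to 6742393 was number 2 in replicate 1, and its counterpart at 6742014 to 6742364 was number 3 in replicate 2. Counterparts at 6737555 to 6737997 and 6737609 to 6737884 were numbers 13 and 22. Combined peaks flanked these regions at 6735574 to 6736127 (q = 2.18e-08) and 6745437 to 6745877 (q = 7.6e-14).

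**Figure D3:**
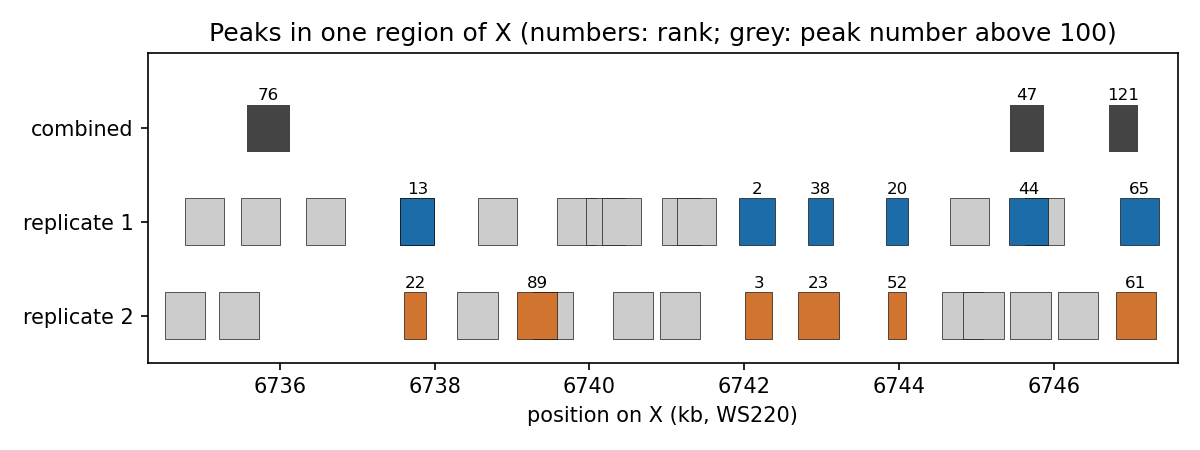
Peaks of the combined list and of both ChIP replicates on X around position 6741934 (x axis, kb on WS220; rows are lists). Numbers give the rank by q-value or the peak number, and replicate peaks numbered above 100 are grey; replicate peaks 2, 13, 20 and 38 of replicate 1 and 3, 22, 23, 52 and 89 of replicate 2 stand where the combined list as analysed here has no peak.

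The third comparison set the density of peaks on X against the autosomes. X carried more combined peaks than its length would give: 113 of 396 (28.5%, 24.1 to 33.3%) against 17.7% of the genome span (two-sided exact binomial p = 1.06e-07). This was 6.38 peaks per Mb and 1.61 times the number expected by length. Chromosome I carried fewest, with 31 peaks, 2.06 per Mb and 0.521 times expectation (Benjamini-Hochberg adjusted exact binomial p = 6.51e-05 over 6 chromosomes). The other autosomes ranged from 3.39 per Mb on V to 4.13 per Mb on II, with adjusted exact p-values from 0.311 to 0.895. Among the first 396 peaks by peak number, X held 114 in replicate 1 (28.8%, exact binomial p = 5.11e-08) and 26.3% in replicate 2 (exact binomial p = 2.22e-05). With score ties broken by position, replicate 2 had 80 of 396 on X (20.2%, exact binomial p = 0.188), where the 33 tied peaks left out were all on X. The low count on chromosome I was not seen in the replicate lists, which held 51 and 65 peaks there (adjusted exact p = 0.312 and 0.527).

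**Figure D4:**
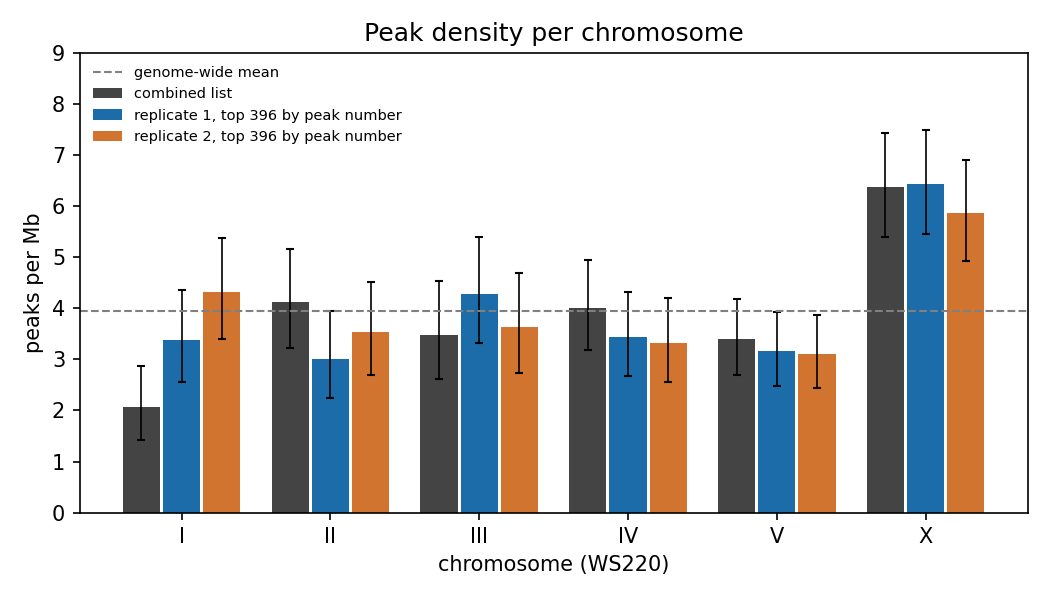
Peaks per Mb (y axis) on each chromosome (x axis) for the combined list and for the first 396 peaks by peak number of each ChIP replicate. Error bars are exact binomial 95% intervals and the dashed line is the genome-wide mean; X stands at 6.38, 6.44 and 5.87 peaks per Mb, and the combined list is lowest on chromosome I at 2.06.

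The fourth comparison set autosome centres against arms. Combined peaks were concentrated in the central 33.3% of the autosomes, which held 140 of 283 autosomal peaks (49.5%, 43.5 to 55.5%, two-sided exact binomial p = 2.19e-08). The replicate lists ranked by peak number gave 160 of 282 (56.7%) and 146 of 292 (50.0%). The 33.3% is a share by length and takes no account of gene density or other background along the autosomes, which was not tested. The difference among autosomes in this share was near the threshold, with a permutation p of 0.0245 over single peaks and of 0.0467 over the 203 autosomal loci left after merging peaks within 10 kb (100000 permutations each). Centres held 43 of 71 peaks on V (60.6%, adjusted exact p = 1.62e-05) and 39 of 70 on IV (55.7%, adjusted exact p = 0.000452), with adjusted exact p-values of 6.67e-05 and 0.0252 over loci. On II they held 22 of 63 (34.9%, 23.3 to 48.0%), on III 20 of 48 (41.7%, 27.6 to 56.8%) and on I 16 of 31 (51.6%, 33.1 to 69.8%), none of which passed the adjusted exact test (p = 0.79, 0.279 and 0.0605). X held 39 of 113 in its central part (34.5%, 25.8 to 44.0%, exact binomial p = 0.842).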

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

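No paired analysis was possible because the input samples that share replicate numbers with the ChIP samples have no values analysed here. The overlap of the first 396 peaks, 21.7%, ranged from 15.7% (first 792 peaks) to 23.5% (peak number) and stayed beyond the shifts in all 5 alternatives. The shares of combined peaks found in each replicate also stayed beyond the shifts under every alternative; a 50% reciprocal overlap lowered them to 41.2% and 35.9% for the full lists and to 25.5% and 17.2% for the first 396, and the first 792 gave 47.7% and 35.4%. The score correlation across matched pairs was 0.08 overall and 0.30 in the first 396 of replicate 1, where most scores were tied, and had no value for the 209 pairs from replicate 2, whose scores were all tied; untied peak numbers, added after seeing the data, gave 0.61 and 0.63. With a single replicate list in the designed ranking, the X share was 20.2% (replicate 2) and 29.5% (replicate 1). The first of these lost its call (exact binomial p = 0.188) through the tie rule, since all 33 tied peaks left out were on X; ranking by peak number gave 26.3% and 28.8%. The 198 strongest combined peaks kept the X excess (27.3%) and the excess in autosome centres (52.8%). The central 50% of the span, run for autosome centres only, held 66.1%. Alternatives chosen after seeing the data also kept both: peaks within 10 kb merged (29.5% and 48.3%), peaks of 100 bp or wider (28.7% and 49.6%) and peaks found in both replicates (32.4% and 50.5%). Designed tests of promoters, gene lists and the E-box, with 10 alternatives, were not run. Depth is unknown, so peaks missing from one replicate cannot be called unbound.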

Other observations

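Of the tests in this part, merging neighbouring peaks and widening narrow ones were written down before their results were seen, and the others after; a width in the widening test was later reworded without moving its bound, and the deciding value for weak peaks was changed from a share to its p-value after both were seen. Combined peaks lay in clusters: the 396 peaks formed 288 loci when peaks within 10 kb were merged, so that 108 peaks joined a neighbour, against a mean of 17.2 and a highest value of 31 in 1000 uniform placements on the same chromosomes (permutation p = 0.001, the smallest these placements can give). The locus with the most peaks was on X at 13350113 to 13360204, with 9 peaks in 10.1 kb and a best q-value of 1.47e-30. Loci with 6 peaks lay on V at 19521705 to 19530451 and on X at 17631012 to 17641119. The combined peaks starting at 11961524 on IV and at 6897019 on III belonged to loci of 5 and 4 peaks.

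X held 28.5% of the combined peaks against 17.7% of the span. Counting clusters several times is argued against as the whole cause, because X still held 29.5% of the 288 loci (exact interval 24.3 to 35.1%). A chromosome-wide bias of equal size in weak and strong peaks is also argued against as the whole cause. X held at most 20.2% of the weakest 10000 peaks of a replicate, below the 24.1% lower bound of the combined share. Those weak peaks still lay above 17.7%, so a bias of that kind may account for part of the excess. A bias that grows with peak strength stays open. The X share fell from 37.0% and 28.0% in the first 100 peaks of replicates 1 and 2 to 20.2% and 19.6% in the weakest 10000. The replicate lists also come from a different peak caller than the combined list. No biological explanation was tested, since the series has one strain and one stage.

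Replicate peaks numbered 2 and 3 on X at 6741934 to 6742393 and 6742014 to 6742364 had no peak in the combined list as analysed here. The smallest gap from a first-100 replicate peak without overlap in this region to a combined peak was 1316 bp, over 2 replicate peak widths of 504 bp. This gap test cannot decide whether peaks were absorbed into a neighbouring combined peak. An absorbed peak would overlap a combined peak, and peaks with overlap were left out. A first form of this test also counted first-100 replicate peaks that overlap a combined peak and gave a smallest gap of 0 bp, which by its rule would have favoured absorption; those peaks were left out after that value was seen, because they do not lack a combined peak. A general disagreement between callers at strong sites stays open: the 0% of the other 34 pairs in the first 50 of both replicates that lacked a combined peak follows from drawing the region around the 3 pairs that did, and outside the region 7 of 94 first-100 peaks of replicate 1 and 25 of 94 of replicate 2 also lacked one. A local difference between the lists, such as a filter or the control signal there, also stays open and was not tested.

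Combined peaks without a peak in one or both replicates numbered 121 (30.6%). Weakness near the q-value threshold is consistent with this, since 93 of the 198 weakest lacked one against 28 of the 198 strongest (two-sided Fisher's exact p = 1.11e-12), but weaker peaks were also narrower, with a median of 472 bp over the strongest 99 and 134 bp over the weakest 99. Among peaks of median width or wider, 15 of 39 weaker against 16 of 160 stronger ones lacked one (Benjamini-Hochberg adjusted two-sided Fisher's exact p = 0.000128), and among narrower peaks 78 of 159 against 12 of 38 did (adjusted exact p = 0.0693). Width may contribute as well: within the weakest 198, 59 of 99 narrower against 34 of 99 wider peaks lacked one (two-sided Fisher's exact p = 0.000596). As the whole cause it is argued against, since widening all combined peaks to at least 504 bp left 22.2% (18.2 to 26.6%) without one.

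Chromosome I held 31 combined peaks, against 51 and 65 among the first 396 of replicates 1 and 2. Two-sided Fisher's exact tests gave adjusted p = 0.0262 and 0.000583, but the lists share peaks, so they are not independent. Chromosome I was also picked after it was seen to hold the fewest combined peaks. The adjustment covers replicates 1 and 2 only and does not allow for that choice among chromosomes, so no conclusion is drawn from these p-values.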
